A study of Homo sapiens with 20 samples.

How the data were processed

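The series holds RNA sequencing of human adipocytes differentiated in culture from supraclavicular (SClav) and abdominal subcutaneous (AbdSQ) biopsies and treated with saline or norepinephrine (NE) for 4 h, with 5 libraries in each of 4 groups. Per the labels, libraries were made with a TruSeq stranded mRNA kit and all samples were prepared concurrently. The submitters' processing notes name TopHat2 and the genome build hg38 (GRCh38), and the aligner's version, the counting tool, its strand setting and its annotation are not given in the sources used here. The deposited table gives one signal per gene and library, which is a read count divided by one size factor per library. This was tested on the table: multiplying each column by a single factor gave whole numbers for 100% of its values (tolerance 0.01), and these factors equalled the median-of-ratios size factors of DESeq2 (ratio 1). The recovered reads lay between 23.2 and 39.7 M per library, and 3 reads in a library, the floor used here, correspond to a deposited value of 2.44 to 4.60. Counting intervals and floors cover counting error only.

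The table has 60107 identifiers, of which 40995 were paired with a symbol by a gene name table and 56531 by GENCODE v29, whose GRCh38 coordinates are given, and 3576 had no symbol. A total of 19123 genes were at 0 in every library. Y-linked genes, XIST and TSIX (513 identifiers) were left out. edgeR's expression filter kept 19015 genes. The test was limma-trend with robust empirical Bayes on log2(value + 1) over all 20 libraries, with 4 group means and Benjamini-Hochberg adjustment at 0.05 within each comparison. The comparisons were NE against saline in each depot, SClav against AbdSQ under each treatment, and the difference of the NE effects (the interaction). The pseudocount of 1 shrinks the fold changes of genes with few reads. Fold changes are differences of mean log2 values, so they can still exceed the ratio of mean levels where libraries of a group differ widely. The design had been written for read counts and edgeR's quasi-likelihood test, and since the table holds normalised values, the limma test written for that case was used and edgeR on recovered reads was added as an alternative. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

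The comparisons, alternatives, gene lists and the rule for naming genes were chosen before the data were examined, apart from those said to have been chosen after seeing the data. The rule named the 8 largest increases and decreases per comparison among genes past the threshold, with a mean of at least 1 log2 CPM and no overlap between the groups, passing over genes without a proper symbol, pseudogenes, small RNAs, HLA, immunoglobulin and mitochondrial genes. It also named UCP1 in every comparison, list members past the threshold, and for the interaction the 5 smallest p-values when fewer than 3 genes qualified. ENSG00000223414, AC091182.1 and PDE10A lie outside the rule. The result for 1 gene that the rule named is not reported here.

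Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, on log2(value + 1) in place of log2 CPM, and adjusted over the 29 lists tested, 21 of pathways and 8 of markers of other cell types. Each list was also tested with its own estimated correlation and with fry, and each member was adjusted both over all genes and over the list alone. A list of 5 erythroid markers was not tested because 0 of them were among the genes tested, and its highest value in any library was 3.69. Lists without a camera call at the preset correlation in any comparison were fatty acid and triglyceride synthesis, cholesterol synthesis, adipocyte identity, fatty acid oxidation, glycolysis, interferon response, lipolysis, circadian clock, cell cycle, positional regulators and 7 of the 8 marker lists. Fatty acid and triglyceride synthesis and fatty acid oxidation genes had 0 members past the limma threshold in any comparison, with camera adjusted p = 0.636 and 0.59 for NE in SClav, 0.313 and 0.614 for NE in AbdSQ, and 0.695 for both between the depots under saline. In SClav with NE the remaining lists without a call gave camera adjusted p = 0.0961 (respiratory chain), 0.0768 (secreted factors), 0.111 (interferon), 0.159 (TGF-beta), 0.295 (posterior HOX), 0.376 (cell cycle), 0.583 (adipocyte identity), 0.636 (clock), 0.864 (glycolysis) and 0.905 (cholesterol, extracellular matrix and positional genes). The marker lists there gave 0.171 (smooth muscle), 0.321 (endothelial), 0.376 (keratinocyte), 0.58 (macrophage), 0.772 (Schwann and neural), 0.864 (skeletal muscle) and 0.905 (fibroblast and mesothelial).

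Quality measures (reads, mitochondrial share, ribosomal protein share, share of the 10 highest genes) were compared with 16 exact permutation tests of 252 splits each. The lowest p was 0.0159, for ribosomal protein genes at 2.93% of reads in SClav and 3.36% in AbdSQ under saline, and it was 0.254 after Benjamini-Hochberg adjustment. The first 2 principal components held 23.1% and 22.5% of the variance, and AbdSQ saline library 17 and AbdSQ NE library 18 lay at -90.9 and -117 on the second, where the lowest other library was at -21.7.

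The test was tried on simulated data in which 200 of 19015 genes were changed. The changed genes were picked above a minimum mean level and all libraries were drawn as unrelated. The rates thus do not cover genes with few reads or libraries that are tied. It recovered 69% of 2-fold and 90% of 4-fold changes for NE in SClav, 70% and 88% for NE in AbdSQ, 68% and 87% for the depots under saline, 71% and 91% for the depots under NE, and 46% and 77% for the interaction, with 6.47%, 5.95%, 0.641%, 4.14% and 1.6% of the calls false.

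Alternatives were edgeR with RLE or upper-quartile factors, no filter and a stricter filter, DESeq2, limma-voom with sample weights, a surrogate variable, a test against a log2 fold change of 0.58 (limma's treat in place of edgeR's), only the 10 libraries compared, and leaving out each library in turn. Chosen after seeing the data were edgeR with TMM, pseudocounts of 0.5 and 5, TMM rescaling, leaving out libraries 17 and 18, leaving out or adding a term for the 4 libraries under 25 M reads, thinning of reads to the smallest library, and a block of consecutive sample numbers.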

Results

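Messenger RNA was sequenced from human adipocytes grown and differentiated in culture from 2 adipose depots, the supraclavicular depot (SClav) and the abdominal subcutaneous depot (AbdSQ). Supraclavicular fat can hold thermogenic adipocytes, which burn fuel to make heat, whereas abdominal subcutaneous fat is mostly white storage fat. The cells received saline or norepinephrine (NE), the transmitter by which sympathetic nerves switch on lipolysis and heat production, for 4 h. There were 4 groups of 5 libraries, and libraries are named here by their group and their sample number from 1 to 20. The deposited table held 60107 gene identifiers, and 19015 genes were expressed highly enough to be tested. The libraries held 23.2 to 39.7 M recovered reads. SClav NE libraries 2, 4 and 6 and SClav saline library 3 lay under 25 M, SClav saline library 5 held 30.2 M, and the rest held 37.9 M or more. The labels do not say that the libraries of a group came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical. Each of the 20 libraries correlated best with its neighbour in sample number, a library of the same depot and the other treatment. Part of that spread may thus be common to such neighbours, while the tests treat all libraries as unrelated. Levels are normalised read counts as mean ± SD over n = 5 libraries, fold changes are on the log2(value + 1) scale with their SE, and adjusted p-values are limma's after Benjamini-Hochberg adjustment.

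NE against saline in SClav adipocytes showed which transcripts move within hours of adrenergic stimulation in the depot with thermogenic potential. UCP1, the mitochondrial uncoupling protein through which brown adipocytes make heat (chromosome 4, 140559434 to 140568805, GRCh38), rose from 113 ± 36.8 to 1780 ± 720, a log2 fold change of 3.95 (SE 0.67, adjusted p = 0.00146). DIO2, the deiodinase that produces active thyroid hormone (chromosome 14, 80197527 to 80387757), rose from 139 ± 75.1 to 1355 ± 672 (log2 fold change 3.35, SE 0.48, adjusted p = 0.000341). The transcription factor IRF4 rose from 59.5 ± 36.0 to 1884 ± 1140 (log2 fold change 4.92, SE 0.70, adjusted p = 0.000324). HAS1, a hyaluronan synthase, rose from 13.0 ± 11.1 to 955 ± 757 (log2 fold change 6.06, SE 0.96, adjusted p = 0.000821). The other large increases were those of the deubiquitinase USP2 (log2 fold change 4.43), C2orf66 (4.25), the nuclear receptor NR4A3 (4.14), the T-cell adaptor SH2D2A (4.05) and the inhibitor of DNA binding ID3 (3.89). In all, 577 genes rose and 286 fell, of which 259 rose and 74 fell by 2-fold or more.

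One transcript named only by its identifier, ENSG00000223414, was singled out after its values were seen because it went from almost no reads to a moderate level in both depots. In SClav it had 1 read over the 5 saline libraries and 1626 reads over the 5 NE libraries, a ratio of 1950 with a 95% counting interval of 350 to 77200 that covers counting error only. In AbdSQ it had 36 and 741 reads, and its level went from 6.63 ± 13.8 to 136 ± 44.5. Of the 36 saline reads 34 came from AbdSQ saline library 17, without which the log2 fold change of ENSG00000223414 was 6.64 in AbdSQ and the difference between the depots 1.69. On the log2(value + 1) scale the changes were 8.33 (SE 0.70, adjusted p = 7.63e-07) in SClav and 5.72 (SE 0.70, adjusted p = 0.000826) in AbdSQ. The difference between the depots, 2.62 (SE 0.99), did not pass the test (adjusted p = 1). For ENSG00000223414 its size depends on the model: it was 5.93 with edgeR (adjusted p = 1), 6.15 with DESeq2 (adjusted p = 0.441) and 2.02 with voom (adjusted p = 1). EdgeR gave changes of 10.28 in SClav and 4.35 in AbdSQ. The long non-coding RNA LINC00473 named in the series title was paired with 0 identifiers of the table by the name tables used here and was not analysed under that name. Whether ENSG00000223414 is that gene was not settled by these tables. RefSeq places it on chromosome 6 from 165924048 to 165988039 (GRCh38.p14), inside the interval of PDE10A. PDE10A, a phosphodiesterase gene named after its values were seen, was at 428 ± 144 and 1084 ± 367 in SClav and at 111 ± 70.7 and 279 ± 181 in AbdSQ with saline and NE, and neither NE effect passed (adjusted p = 0.195 and 0.462), though that in SClav passed with voom (adjusted p = 0.0259).

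**Figure D1:**
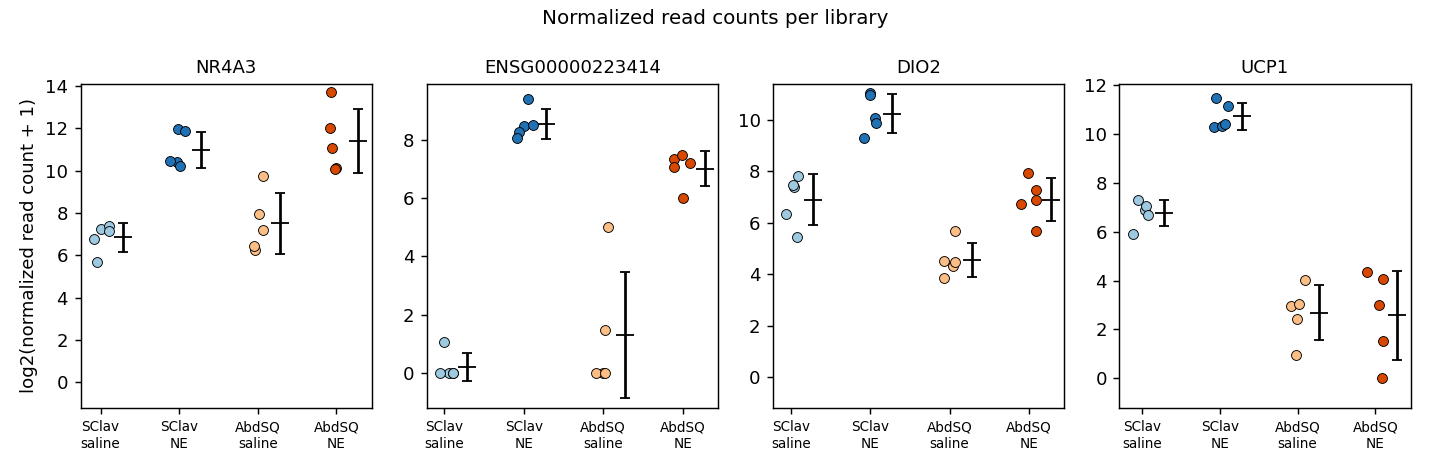
Normalised read counts per library on a log2(value + 1) axis for NR4A3, ENSG00000223414, DIO2 and UCP1 in the 4 groups, where each point is 1 library and the bar beside the points gives the mean ± SD of the 5 libraries. NR4A3, ENSG00000223414 and DIO2 were higher with NE in both depots, whereas UCP1 was higher with NE in SClav (log2 fold change 3.95) and not measurably so in AbdSQ (-0.09, adjusted p = 0.998).

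Camera called 6 of the 29 gene lists in this comparison, and none of these calls held with an estimated inter-gene correlation, where each of the 6 lists had an adjusted p of 0.714. Of 19 measured cAMP and CREB early response genes, 6 rose and 0 fell (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.09e-06), among them CREM (log2 fold change 2.25), NR4A3 and the phosphodiesterase PDE4D (2.07), which breaks down cAMP. Of 21 thermogenic adipocyte genes, 6 rose and 0 fell over all genes and over the list alone (camera adjusted p = 0.00102), including UCP1, DIO2, IRF4 and the glycerol kinase GK (1.82). Of 20 adrenergic receptor and protein kinase A genes, 1 rose, the regulatory subunit PRKAR1A (0.68, SE 0.15), and 4 rose adjusted over the list alone (camera adjusted p = 0.00811). Of 22 unfolded protein and integrated stress response genes, 2 rose, the amino acid transporter SLC7A5 (1.72) and the endoplasmic reticulum protein MANF (0.57), and 4 rose adjusted over the list alone (camera adjusted p = 0.00154). Of 23 inflammatory genes, the cytokine IL1B rose (1.54, SE 0.37), and 1 rose adjusted over the list alone (camera adjusted p = 0.0249). The anterior HOX genes were called lower (camera adjusted p = 0.0259): HOXB3 fell (-0.85, SE 0.24), 12 of 13 did not pass, and over the list alone 1 rose and 2 fell.

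Several lists that camera did not call still held single genes that changed. Of 19 circadian clock genes, 3 rose and 2 fell, over all genes and adjusted over the list alone. The repressor CRY1 (log2 fold change 1.20) and NFIL3 (0.96) were among those that rose, and DBP (-1.41) and the nuclear receptor NR1D1 (-0.94) fell. Of 21 interferon response genes, OASL rose (3.15) and 3 fell, among them IFIT2 (-0.92) and IFI44 (-0.75), with the same counts adjusted over the list alone. Secreted factors that rose were the hormone STC1 (3.73), the growth factor FGF7 (1.72) and the peptide APLN (1.04), 3 of 31, with 5 adjusted over the list alone. ID3, ID2 (1.17) and PMEPA1 (0.96) were the 3 of 20 TGF-beta and SMAD target genes that rose, over all genes and over the list alone. The positional regulators PITX1 (2.56) and EN1 (0.86) rose, 2 of 28 by either adjustment. Of 17 lipolysis and lipid droplet genes, the lipase inhibitor ANGPTL4 rose (1.56), and 5 rose adjusted over the list alone (camera adjusted p = 0.0506). Cytochrome c, CYCS (0.76), was the 1 of 32 respiratory chain genes that rose by either adjustment, and 0 of 24 adipocyte identity genes changed. The mitotic kinase AURKA rose (0.86), 1 of 21 cell cycle genes, while 1 rose and 1 fell adjusted over the list alone.

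The largest decreases among genes whose 5 NE values all lay below the 5 saline values were those of the semaphorin SEMA4B (log2 fold change -1.88), the urokinase PLAU (-1.81), the death ligand TNFSF10 (-1.62), BAHCC1 (-1.52), DBP, the protease ADAMTS10 (-1.35), MYO7B (-1.34) and ARHGEF37 (-1.30). SEMA4B went from 594 ± 81.5 to 162 ± 30.4 (SE 0.37, adjusted p = 0.0053), and PLAU from 511 ± 199 to 151 ± 66.7 (SE 0.35, adjusted p = 0.00417). Among markers of other cell types, MYOCD, a coactivator of smooth muscle genes, rose from 3.32 ± 1.40 to 80.8 ± 27.6 (4.23, SE 0.40, adjusted p = 2.51e-06) and the smooth muscle protein CNN1 rose (1.89, SE 0.51, adjusted p = 0.0369), 2 of 10 smooth muscle and pericyte markers by either adjustment. None of the other 7 marker lists tested had a member past the threshold or a camera call.

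The shallow libraries were unevenly spread over this comparison, with 3 of the 5 SClav NE libraries and 1 of the 5 SClav saline libraries under 25 M reads. Without these 4 libraries 89 genes passed in place of 863, and with a term for them 486 passed, both alternatives chosen after seeing the data. Leaving out SClav NE library 2, SClav saline library 7 or SClav saline library 9 gave 503, 560 and 541 genes. Of 44 named genes past the threshold here, 29 passed whichever single library was left out, and the calls of MANF, APLN, SLC7A5, HOXB3, AURKA, ARHGEF37, CNN1, FGF7 and IFI44 ended in 5 to 9 of the 10 such fits. With edgeR, SLC7A5 (adjusted p = 0.0549) and HOXB3 (adjusted p = 0.065) did not pass. MANF did not pass with RLE factors in edgeR (adjusted p = 0.0506), nor APLN (adjusted p = 0.0744) and CNN1 (adjusted p = 0.0598) with a surrogate variable.

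**Figure D2:**
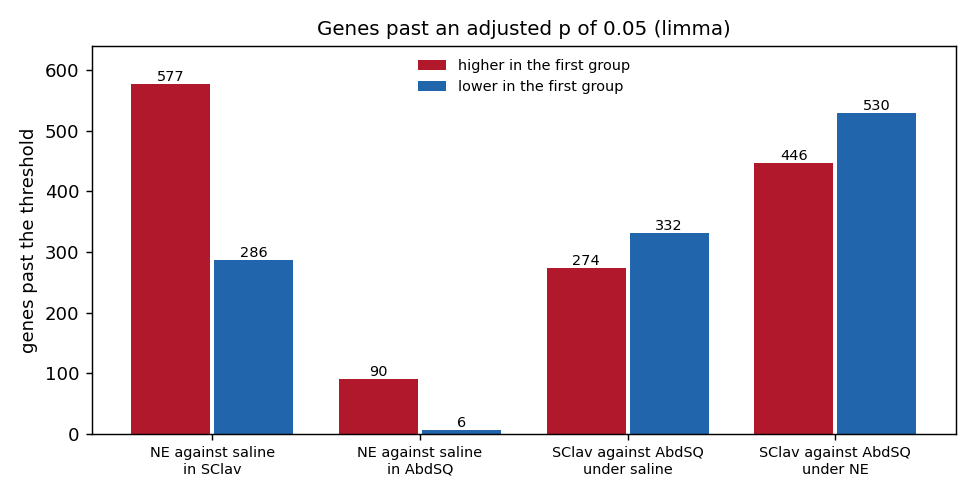
Number of genes with a limma adjusted p under 0.05 in the 4 comparisons of 5 against 5 libraries, split into genes higher (red) and lower (blue) in the first-named group. NE against saline gave 577 and 286 genes in SClav and 90 and 6 in AbdSQ.

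In AbdSQ adipocytes, the same treatment raised 90 genes and lowered 6. NR4A3 rose from 282 ± 332 to 4350 ± 5170 (log2 fold change 3.89, SE 0.68, adjusted p = 0.0102), and the hormone STC1 from 273 ± 292 to 3363 ± 4070 (3.38, SE 0.70, adjusted p = 0.0303). C11orf96 rose from 241 ± 109 to 2377 ± 1750 (3.09, SE 0.44, adjusted p = 0.00232), and CTH, the enzyme cystathionine gamma-lyase (chromosome 1, 70411218 to 70439851), from 419 ± 70.0 to 1739 ± 836 (1.96, SE 0.28, adjusted p = 0.00254). UCP1 was at 6.92 ± 5.31 with saline and 8.79 ± 8.50 with NE, a log2 fold change of -0.09 (SE 0.67, adjusted p = 0.998), and its sign was positive in several other fits. DIO2 rose from 24.9 ± 14.3 to 134 ± 72.5 (2.35, SE 0.48, adjusted p = 0.0305).

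Further increases were those of GPRC5A, an orphan receptor (log2 fold change 2.60), SGIP1 (2.23), ARID5A (1.91) and the RNA-binding protein SAMD4A (1.79). The named decreases were TNFSF10 (-1.34, SE 0.29), the phosphatase SSH2 (-0.70, SE 0.14) and the adaptor subunit AP4B1 (-0.40, SE 0.09), the last with an adjusted p of 0.0498. Camera called 5 of 29 lists higher with NE, and each had an adjusted p of 0.643 with an estimated correlation. Of the cAMP and CREB early response genes, 1 of 19 rose and 9 rose adjusted over the list alone (camera adjusted p = 1.06e-10), and CREM, with a log2 fold change of 1.02, did not pass over all genes (adjusted p = 0.101), but passed with DESeq2 (adjusted p = 0.00666) and with a surrogate variable (adjusted p = 0.0329). The inflammatory genes (0 of 23 past the threshold by either adjustment, camera adjusted p = 7e-06), the stress response genes (0 of 22, 1 adjusted over the list alone, camera adjusted p = 1.99e-05), the TGF-beta and SMAD target genes (0 of 20, 4 up and 1 down adjusted over the list alone, camera adjusted p = 0.0156) and the secreted factor genes (STC1, 1 of 31 by either adjustment, camera adjusted p = 0.0197) were the others.

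The thermogenic list was not called here (camera adjusted p = 0.0904): DIO2 rose, 3 of 21 rose adjusted over the list alone, and IRF4 (2.89, SE 0.70, adjusted p = 0.0793) and GK (0.98, SE 0.27, adjusted p = 0.139) did not pass over all genes. IRF4 passed with DESeq2 (adjusted p = 0.0316), with a surrogate variable (adjusted p = 0.0114) and without AbdSQ NE library 16 (3.29, adjusted p = 0.0394) or AbdSQ saline library 17 (3.51, adjusted p = 0.00885), and GK passed with DESeq2 (adjusted p = 0.0138). The 3 other alternatives gave 0.121 to 0.147 for IRF4, and the 4 others 0.0769 to 0.125 for GK. No marker list of another cell type was called in this comparison. Without the 4 shallow libraries, all of them SClav, 87 genes passed. When only the 10 AbdSQ libraries were fitted, 14 genes passed, and leaving out AbdSQ saline library 11, 13, 15 or 19 or AbdSQ NE library 14, 18 or 20 gave 50, 48, 50, 50, 45, 63 and 53 genes. Of 13 named genes past the threshold, 6 passed whichever single library was left out, and the calls of DIO2, GPRC5A, STC1, TNFSF10, SSH2 and AP4B1 each ended in 6 or more of the 10 such fits. DIO2 (adjusted p = 0.147) and GPRC5A (adjusted p = 0.0603) did not pass with voom, nor AP4B1 with RLE factors in edgeR (adjusted p = 0.0518). Without AbdSQ NE library 18 the log2 fold change of STC1 was 2.79.

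The responses of the depots were compared gene by gene, since a count past a threshold in one depot and not in the other does not show a difference. A total of 81 genes rose in both depots, where 2.73 would be shared by independent sets of these sizes, 4 fell in both (0.0902 for independent sets), and 0 went in opposite directions. All 96 genes called in AbdSQ had the same sign in SClav, and 68 of them had a larger change there. Their median size was 1.41 in SClav and 1.34 in AbdSQ on the log2 scale. Of the 863 genes called in SClav, 852 had the same sign in AbdSQ, with a median size of 0.83 in SClav and 0.43 in AbdSQ. Part of that gap follows from choosing genes by their SClav values. Across genes, which are not independent replicates, the fold changes had a Spearman correlation of 0.673. Without the 4 shallow libraries 45 genes were shared, and leaving out AbdSQ saline library 11, 13, 15 or 19 or AbdSQ NE library 14 or 20 gave 48, 44, 47, 47, 43 and 49.

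**Figure D3:**
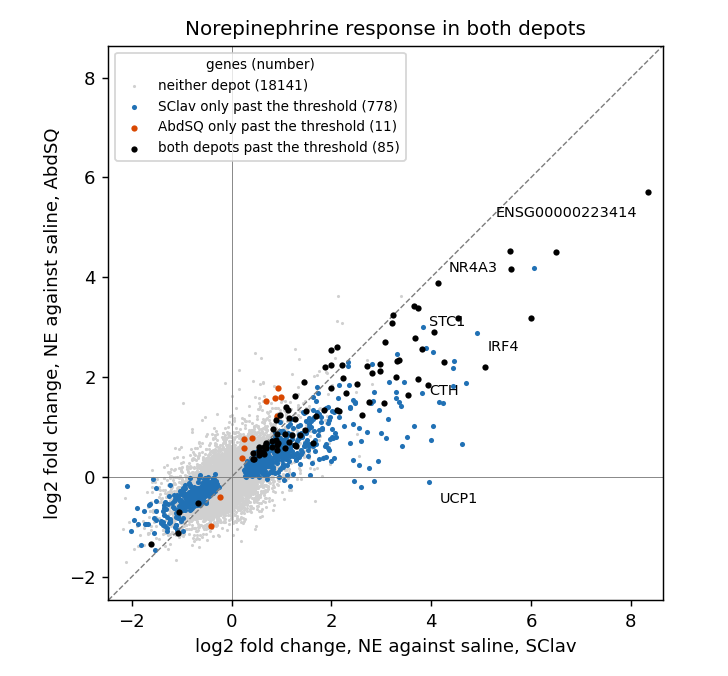
Log2 fold change with NE in SClav (x axis) against AbdSQ (y axis) for the 19015 genes tested, coloured by the depot in which a gene passed a limma adjusted p of 0.05, with the dashed line marking equal change. The 85 genes past the threshold in both depots (black) all changed in the same direction, and UCP1 lies near 0 on the AbdSQ axis.

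The test of the difference itself asked which genes respond to NE otherwise in SClav than in AbdSQ. The labels give no pairing of saline with NE libraries, so the fit treats all libraries as unrelated. Its count holds only under that assumption. The data cast doubt on it, since each of the 20 libraries correlated best with its neighbour in sample number (r from 0.615 to 0.869 over 5000 genes). With a block of consecutive sample numbers, chosen after seeing the data, 202 genes passed, and the named genes were not followed in that fit. The fit without a block called 1 gene, the non-coding transcript AC091182.1 (ENSG00000253123, chromosome 8, 37326575 to 37331984), named because it was the only call, after its values were seen. Its level went from 2.89 to 99.7 in SClav and from 0 to 0.71 in AbdSQ, where it had 0 reads with saline and 4 with NE. Its fitted difference of 3.95 on the log2(value + 1) scale (SE 0.56, adjusted p = 0.0209) depends on the pseudocount at such levels. The call ended in 11 of the 20 fits that left out a single library, those without SClav NE library 2, 6 or 10, SClav saline library 3, AbdSQ saline library 11, 13, 15, 17 or 19, or AbdSQ NE library 18 or 20, and it was not made by edgeR or DESeq2 (adjusted p = 1 in both) or voom (adjusted p = 0.935). With edgeR 0 genes passed. A total of 346 genes with limma and 341 with edgeR had an unadjusted p under 0.05. Chance alone would give a share of about 0.05 of the 19015 genes, which is more. Ties between saline and NE libraries, left in the spread of this fit, could give such a deficit, but this was not tested directly. DESeq2 called 7 genes.

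UCP1, named in advance, differed by 4.04 (SE 0.95) and did not pass the test (adjusted p = 0.974 with limma and 1 with edgeR), but it passed with DESeq2 (3.62, adjusted p = 0.0213). The genes with the smallest p-values among well expressed genes were also short of the threshold: the mitochondrial phosphatase PPTC7 differed by 0.94 (SE 0.18, adjusted p = 0.42), CTH by 1.78 (SE 0.40, adjusted p = 0.907), the caspase CASP9 by 1.39 (SE 0.34), PGAP1 by 1.26 (SE 0.32) and ARHGAP20 by 0.81 (SE 0.20), the last 3 with an adjusted p of 1. PPTC7 went from 1853 ± 115 to 5781 ± 1110 in SClav and from 2097 ± 353 to 3341 ± 347 in AbdSQ. MYOCD differed by 2.75 (SE 0.56, adjusted p = 0.491). PPTC7 (adjusted p = 0.00813) and MYOCD (adjusted p = 0.0287) passed with DESeq2 and with none of the 4 other alternatives run for them, which gave 0.0776 to 0.66 for PPTC7 and 0.436 to 0.788 for MYOCD. UCP1 had 0.267 to 1 in those 4, and its difference was 3.40 (adjusted p = 0.549) without AbdSQ NE library 18. As sets, the thermogenic adipocyte genes (18 of 21 with a larger value in SClav, median 0.31, camera adjusted p = 0.00115) and the respiratory chain genes (30 of 32, median 0.11, camera adjusted p = 0.0257) were called. Both had an adjusted p of 0.954 with an estimated correlation, and 0 members passed over all genes, while 1 thermogenic gene and 0 respiratory chain genes passed adjusted over the list alone.

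The comparison of SClav with AbdSQ adipocytes under saline showed how the depots differ before stimulation. HOXC10, a homeobox gene of posterior body segments (chromosome 12, 53985065 to 53990279), was at 2.69 ± 2.39 in SClav and 745 ± 126 in AbdSQ, a log2 fold change of -7.95 (SE 0.61, adjusted p = 2.5e-07). NRN1, a neuritin (chromosome 6, 5997999 to 6007605), was at 42.2 ± 34.4 and 3598 ± 646 (-6.90, SE 0.77, adjusted p = 1.89e-05). UCP1 was higher in SClav, at 113 ± 36.8 against 6.92 ± 5.31 (4.08, SE 0.67, adjusted p = 0.0011), and EBF2, a factor of brown precursor cells, was at 3460 ± 671 against 871 ± 521 (2.14, SE 0.31, adjusted p = 0.000284). The collagen COL3A1 was lower, at 67360 ± 10800 against 179300 ± 27400 (-1.41, SE 0.15, adjusted p = 1.58e-05). In all, 274 genes were higher and 332 lower in SClav, 210 and 208 of them by 2-fold or more.

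The posterior HOX genes were lower in SClav almost as a block, 14 of 16 over all genes and 16 of 16 adjusted over the list alone (camera adjusted p = 3.19e-39, and adjusted p = 7.76e-05 with an estimated correlation). HOXA10 differed by -3.79 (SE 0.33) and HOXC6 by -2.83 (SE 0.26). Anterior HOX genes went both ways and were not called: HOXA4 (2.02) and HOXA2 (1.84) were higher, HOXB5 (-2.12) was lower, and 4 were higher and 2 lower adjusted over the list alone. Among 28 positional regulators, 3 were higher and 6 lower (8 and 8 adjusted over the list alone, camera adjusted p = 0.149), with IRX1 (-5.23), IRX2 (-4.78) and IRX5 (-4.63) lower. LHX8, a homeobox gene, had 431 reads over the SClav saline libraries and 1 over the AbdSQ saline libraries, a ratio of 468 with a 95% counting interval of 83.5 to 18500. Several HOX genes and HAND2 lie beside antisense transcripts, and the sources used here do not give the strand setting of the authors' counting, so reads of such pairs may be shared.

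**Figure D4:**
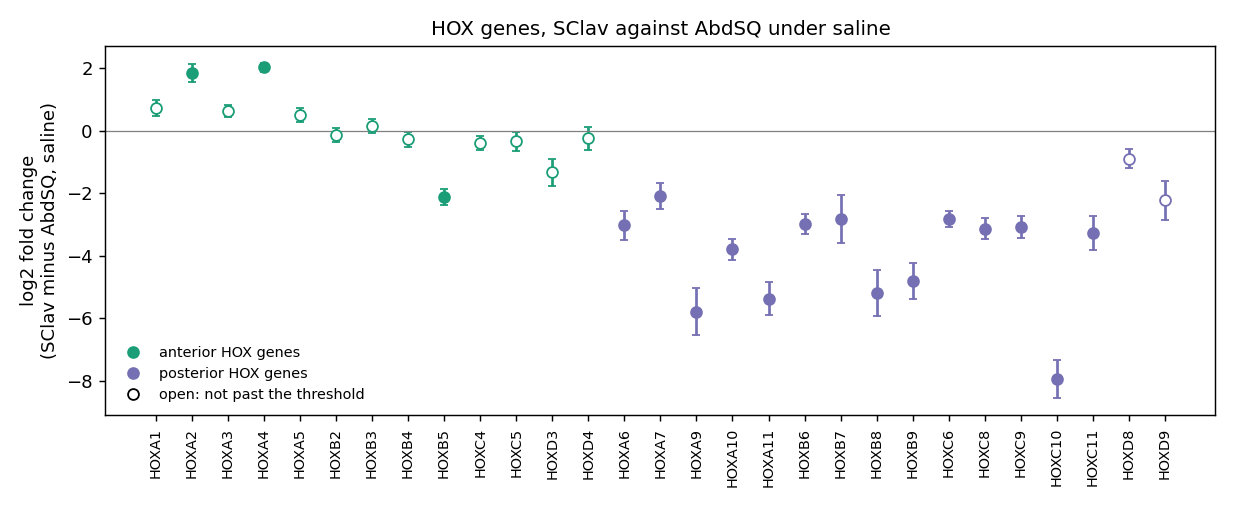
Log2 fold change of the measured anterior (green) and posterior (purple) HOX genes, SClav minus AbdSQ under saline, where points are limma estimates from 5 libraries per group, bars are ± 1 SE and open points did not pass an adjusted p of 0.05. Of the 16 posterior genes 14 were lower in SClav, and anterior genes went both ways.

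Extracellular matrix genes were lower in SClav, 8 of 29 with 0 higher (10 adjusted over the list alone, camera adjusted p = 2.03e-07, and adjusted p = 0.337 with an estimated correlation), among them COL3A1, the collagen COL12A1 (log2 fold change -1.69) and the matrix glycoprotein TNC (-3.30). Smooth muscle and pericyte markers were lower too, 4 of 10 by either adjustment (camera adjusted p = 0.00363, and adjusted p = 0.337 with an estimated correlation), with ACTA2 (-1.44), TAGLN (-1.85), CNN1 (-2.17) and MYOCD (-2.56). Thermogenic adipocyte genes were higher, 4 of 21 with 0 lower (5 adjusted over the list alone, camera adjusted p = 0.00675, and adjusted p = 0.394 with an estimated correlation), with UCP1, EBF2 and DIO2 (2.35). Respiratory chain genes were called higher with 0 of 32 past the threshold by either adjustment and a median of 0.13 (camera adjusted p = 0.0363, and adjusted p = 0.858 with an estimated correlation). The cAMP and CREB early response genes were called lower, with 1 of 19 lower, the phosphodiesterase PDE4B (-1.78), and 2 adjusted over the list alone (camera adjusted p = 0.0363, and adjusted p = 0.858 with an estimated correlation). AbdSQ saline library 17 held the highest AbdSQ saline values of PDE4B (565 against 157 to 219) and NR4A3 (864 against 74.7 to 243). PDE4B passed whichever single library was left out, but whether the list call rests on library 17 was not examined.

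Other lists, which camera did not call, held genes that differed between the depots. In the adipocyte identity list the amino acid transporter SLC7A10 was higher (log2 fold change 3.50) and the fatty acid transporter CD36 lower (-1.25), 1 and 1 of 24 by either adjustment. Of 22 glycolysis genes, PKM (0.64) and PFKM (0.59) were higher and HK1 (-0.75) lower, by either adjustment. Of 21 interferon response genes, OAS2 (2.61) and OAS3 (2.15) were higher, with 6 higher and 3 lower adjusted over the list alone. The adhesion molecule VCAM1 (-2.31) was lower, the only call among the inflammatory genes, and among secreted factors BMP4 (1.31) was higher and SLIT2 (-0.83) and CXCL14 (-5.20) lower. The clock gene HLF was higher (2.26), but not with edgeR (adjusted p = 0.12).

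Markers of other cell types moved in both directions. Endothelial markers ROBO4 (log2 fold change 3.73) and CDH5 (3.24) were higher in SClav and EMCN (-3.09) lower, 3 of 8 by either adjustment. Of 12 preadipocyte and fibroblast markers S100A4 was higher (1.18) and THY1 lower (-1.41), and 2 were higher and 2 lower adjusted over the list alone. CD163 (-3.34), a macrophage marker, and MYH2 (-4.58), a skeletal muscle myosin with close paralogs, were lower, each 1 member of its list by either adjustment. The mesothelial marker WT1 was at 56.7 ± 32.8 in SClav and had 0 reads in all 5 AbdSQ saline libraries, at least 102-fold higher against a floor of 3 reads over the AbdSQ group, and CALB2 was lower (-1.34). Schwann, neural and keratinocyte markers had 0 members past the threshold by either adjustment.

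The remaining large differences among genes without overlap between the groups were increases of SDK1 (log2 fold change 4.16), AIF1L (3.97), the sodium, potassium and calcium exchanger SLC24A3 (3.65, SE 0.35), CHST15 (3.01), PNMA2 (2.74), the metallothionein MT1M (2.63), which has near-identical family members, and the imprinted gene MEST (2.62). Decreases were those of HOXA9 (-5.79), HAND2 (-5.57), the collagen COL11A1 (-5.10, SE 0.57), HAND2-AS1 (-4.67) and the collagen COL8A1 (-3.63). HAND2-AS1 did not pass with edgeR (adjusted p = 0.0934) or with DESeq2 (adjusted p = 0.0916), and HAND2 had a log2 fold change of -3.95 with edgeR. Folds of other genes also depended on the model: edgeR gave -7.01 for CXCL14, 7.965 for LHX8, 8.86 for WT1, -5.05 for HOXA9 and 3.545 for SDK1, all still called. HLF did not pass with edgeR (adjusted p = 0.12), nor CHST15 with voom (adjusted p = 0.0509). Leaving out SClav saline library 1, 3 or 5 gave -4.93, -6.49 and -4.70 for HAND2, whose call ended without library 1 or 5, and -3.94, -5.56 and -3.84 for HAND2-AS1. Other folds that 1 library moved by over 1.5 times were those of NRN1 (-6.22 without SClav saline library 1), HOXA9 (-4.88 without SClav saline library 3), LHX8 (4.40 without SClav saline library 9), SDK1 (3.19 without AbdSQ saline library 17), CXCL14 (-6.12 and -4.53 without AbdSQ saline libraries 17 and 19) and CDH5 (2.41 without AbdSQ saline library 19). Leaving out SClav saline library 5, AbdSQ saline library 15 or AbdSQ saline library 19 gave 391, 396 and 403 genes in place of 606, and without the 4 shallow libraries, 1 of which is SClav saline, 434 passed. Of 56 named genes past the threshold, 44 passed whichever single library was left out, and the calls of HAND2-AS1, HLF, CALB2, CHST15, TAGLN and PDE10A (log2 fold change 2.17) ended in 5 to 9 of the 10 such fits.

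Under NE, 446 genes were higher and 530 lower in SClav than in AbdSQ. UCP1 showed the largest named increase on the log2(value + 1) scale, at 1780 ± 720 against 8.79 ± 8.50 (log2 fold change 8.13, SE 0.67, adjusted p = 5.04e-07). DIO2 was at 1355 ± 672 against 134 ± 72.5 (3.35, SE 0.48, adjusted p = 0.000251). The apolipoprotein L family gene APOLD1 was at 1205 ± 1380 against 102 ± 64.1 (3.09, SE 0.52, adjusted p = 0.00111). The actin capping protein TMOD1 was at 375 ± 81.2 against 42.4 ± 7.86 (3.11, SE 0.30, adjusted p = 1.88e-06). NRN1 (-6.93), HOXA9 (-5.50), COL11A1 (-5.47), HAND2 (-5.36), IRX2 (-4.92) and COL8A1 (-3.99) were lower, as under saline, and SDK1 (3.97), AIF1L (3.88), SLC24A3 (3.68) and MCF2L (3.25) were higher. WT1 was at 64.0 ± 50.4 in SClav with 0 reads in all 5 AbdSQ NE libraries, at least 114-fold higher against a floor of 3 reads over that group. Its log2 fold change was 5.71 on the log2(value + 1) scale and 9.03 with edgeR, above that of UCP1 in any alternative.

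Thermogenic adipocyte genes were higher, 8 of 21 with 0 lower (9 adjusted over the list alone, camera adjusted p = 4.62e-06, and adjusted p = 0.229 with an estimated correlation), with UCP1, DIO2 and EBF2 (log2 fold change 2.14). Posterior HOX genes were lower, 15 of 16 (16 adjusted over the list alone, camera adjusted p = 3.04e-33, and adjusted p = 0.000213 with an estimated correlation), led by HOXC10 (-7.63) and HOXA10 (-3.92). Extracellular matrix genes were lower, 8 of 29 (14 adjusted over the list alone, camera adjusted p = 1.09e-08, and adjusted p = 0.314 with an estimated correlation), with COL3A1 (-1.70). Respiratory chain genes were called higher with all 32 positive and a median of 0.25, while 1 passed by either adjustment, CYCS (0.75, SE 0.14; camera adjusted p = 6.35e-05, and adjusted p = 0.862 with an estimated correlation). Smooth muscle markers, 2 of 10 lower and 4 adjusted over the list alone, were not called (camera adjusted p = 0.0761).

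Single genes of other lists differed as well: APLN (log2 fold change 1.75), LHX8 (4.22), CREM (0.94) and IL1B (1.34) were higher, and IRX1 (-6.15), IRF7 (-0.80), SESN2 (-0.75) and the cyclin CCNB1 (-0.88) lower. IL1B did not pass with edgeR (adjusted p = 0.0549). The depot differences under saline and under NE, which share no library, had 185 higher and 268 lower genes in common, where independent sets would share 6.43 and 9.25, with a Spearman correlation of 0.693 across genes. The labels do not say whether saline and NE libraries came from the same donors, so part of that overlap may come from shared donors. SClav NE holds 3 of the 4 shallow libraries: without those 4 libraries 251 genes passed in place of 976, and with a term for them 423 passed, both chosen after seeing the data. Leaving out SClav NE library 6 gave 621 genes, and fitting only the 10 NE libraries gave 501. Folds that 1 library moved by over 1.5 times were those of UCP1 (7.48 without AbdSQ NE library 18), SDK1 (3.20 without AbdSQ NE library 18), NRN1 (-6.08 without SClav NE library 2), LHX8 (3.55 without SClav NE library 10), HAND2 (-4.53, -6.24 and -4.53 without SClav NE libraries 2, 4 and 6) and HAND2-AS1 (-4.13, -5.61 and -3.80 without the same). The call of HAND2 ended without SClav NE library 2 or 6. HAND2 was at -3.66 with edgeR and -3.65 with DESeq2 and kept its call there, while HAND2-AS1 lost its call with edgeR (-3.14, adjusted p = 0.0641) and DESeq2 (-3.14, adjusted p = 0.051). EdgeR gave 6.155 for LHX8 and -6.23 for NRN1, both still called. The calls of LHX8 with voom (adjusted p = 0.0566) and of CREM with RLE factors in edgeR (adjusted p = 0.0528) ended as well. Of 30 named genes past the threshold, 23 passed whichever single library was left out, and the calls of CREM, HAND2-AS1 and IL1B ended in 6 to 8 of the 10 such fits.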

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

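The counts without libraries 17 and 18 and with a term for the shallow libraries, the tests of fibroblast markers against matrix genes and the 3 tests of other cell types below were chosen only after the results they address were seen. Of 319 groups of 5 values tested, 18 held a library set apart from the other 4 by Dixon's ratio, where chance sets apart about 1 in 20 groups, so these do not exceed what chance gives. In SClav saline these were AC091182.1 (ratio 0.719, library 1 at 0.876 against 2.87 to 4.14), HOXB5 (0.749, library 5 at 50.6 against 79.6 to 92.5), IL1B (0.827, library 9 at 235 against 109 to 124), IRX5 (0.713, library 9 at 34.9 against 3.5 to 7.18), MANF (0.859, library 3 at 761 against 491 to 522), PNMA2 (0.792, library 3 at 2390 against 1240 to 1430) and ENSG00000223414 (1, library 5 at 1.1 against 0). In SClav NE they were ID3 (0.787, library 4 at 554 against 282 to 325) and MANF (0.733, library 4 at 1150 against 695 to 796).

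In AbdSQ saline the values set apart were those of COL3A1 (ratio 0.748, library 11 at 133000 against 183000 to 204000), HOXA4 (0.712, library 11 at 32.4 against 38.6 to 41.4), LHX8 (1, library 19 at 0.897 against 0), PDE4B (0.742, library 17 at 565 against 157 to 219) and TNC (0.734, library 19 at 23000 against 9120 to 11700). In AbdSQ NE they were AIF1L (0.724, library 20 at 5.61 against 33.1 to 62.8), CREM (0.724, library 18 at 1860 against 656 to 875), ENSG00000223414 (0.713, library 16 at 62.6 against 132 to 178) and the number of genes detected (0.878, library 18 at 26948 against 28255 to 28436). No library held more than 2 of the 18. Dixon's ratio takes each gene alone and can miss a shift spread over many genes. AbdSQ libraries 17 and 18 lay apart on the second principal component, at -90.9 and -117 where the lowest other was at -21.7. A difference of the NE effects between the depots was called for AC091182.1 (log2 3.95), the thermogenic adipocyte genes (camera adjusted p = 0.00115) and the respiratory chain genes (camera adjusted p = 0.0257). Neither list was called with an estimated correlation (adjusted p = 0.954 for both) or by fry (adjusted p = 0.95 for both).

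Other splits of the same libraries into groups of the same sizes, 100 per comparison with the real one among them, asked whether chance gives counts as large. If the libraries are unrelated, chance can be excluded at 0.05 for NE in SClav and for both depot comparisons. There 1 split gave as many for NE in SClav (863 genes, highest other 577), 1 for the depots under saline (606, highest other 1) and 1 for the depots under NE (976, highest other 37). For NE in AbdSQ 4 splits gave as many (96, highest other 597). That is just under the 0.05 bound, but not all possible splits were drawn, so chance is not taken as excluded there. A split of the AbdSQ libraries with 597 genes, several times the real count, points to a structure of the samples besides treatment. For the interaction 3 splits gave 1 gene or more (real 1, highest other 2), but at a count of 1 this adds little to the adjusted p of that gene, and chance is not taken as excluded for it.

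The first pattern weighed is that more genes passed with NE in SClav (863) than in AbdSQ (96). Thinning all libraries to the reads of the smallest gave 778 and 86, seen before the next test was chosen, as were the counts of 89 in SClav and 87 in AbdSQ without the shallow libraries. In that fit the excess is gone, but SClav has fewer libraries than AbdSQ. A later check took all 50 choices of 2 NE and 4 saline libraries of a depot, with the other depot whole. The median count was 160 in SClav (49 to 1572) and 5 in AbdSQ (1 to 1310), so at equal numbers of libraries the median stayed higher in SClav, with overlapping ranges. With a term for these 4 libraries the SClav count was 4.12 times the AbdSQ count, which argues against a shift common to them as the whole cause. Without libraries 17 and 18 the AbdSQ count was 98, and the SClav count of that fit stayed higher. With a spread shared by both depots, the spread of libraries 17 and 18 widens the error of both NE effects, not that of AbdSQ alone. That fit also has fewer AbdSQ libraries, which by itself lowers a count. It thus cannot decide whether libraries 17 and 18 hold the AbdSQ count down in other ways. A larger response in SClav stays open: of 1839 genes called for the mean effect 1474 (80.2%) changed more in SClav, with a median of 0.16 on the log2 scale and an exact permutation p of 0.163 over 63504 permutations that treat libraries as unrelated. The median residual SD in AbdSQ was 1.15 times that in SClav. The fit of all 20 libraries gives each gene a single spread shared by both depots, however, so both NE effects of a gene have the same SE. A smaller spread in SClav thus cannot raise the SClav count above the AbdSQ count in that fit. Ties between saline and NE libraries, which the labels do not give, also stay open. A block of consecutive sample numbers, chosen after seeing the data, gave 6770 genes in SClav and 4175 in AbdSQ.

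The second pattern is the lower extracellular matrix genes in SClav under saline, a list called by camera at the preset correlation but not with an estimated one (adjusted p = 0.337). Fry called the list (adjusted p = 0.0203). Without AbdSQ library 17, and library 18 with it, the list had a camera adjusted p of 0.000251 at the preset correlation, with 7 genes lower, 0 higher and a median of -0.32 (-0.54 with all libraries), which argues against that library as the whole cause. Fewer fibroblast-like cells stay open: the median of 12 markers exceeded that of the matrix genes by 0.885 on the log2 scale (bootstrap SE 0.34, 10000 draws), less than the SD of the markers (1.06), a bound set after that value was seen in place of 2 bootstrap SEs. The 12 markers had a median of 0.341, with 7 higher and 5 lower in SClav, where that explanation needs them lower. Past the threshold THY1 (-1.41) was lower and S100A4 (1.18) higher. The 4 of 10 smooth muscle and pericyte markers that were lower include ACTA2 and TAGLN, which are also on the TGF-beta and SMAD target list. They need not mark another cell type and do not decide the question. A difference between the depots, which the design names, also stays open.

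The third pattern is that MYH2, CD163 and EMCN, markers of other cell types, were lower in SClav under saline. Muscle cells in AbdSQ cultures would bring other abundant muscle transcripts, but the highest of ACTA1, CKM and TNNT1 there was 2.42% of MYH2. Macrophages would bring PTPRC and TYROBP, the higher of which was 3.21% of CD163, and the summed C1QA, C1QB, C1QC, TYROBP and LYZ were at 15.5 ± 7.58 in AbdSQ and 12.5 ± 4.23 in SClav (exact permutation p = 0.548). LYZ makes up much of that sum and was lower in AbdSQ (7.95 against 9.38). C1QB (5.76 against 2.56), C1QA (1.05 against 0.328) and TYROBP (0.71 against 0.22) were higher there, all with few reads, so the sum is a weak test. More endothelial cells in AbdSQ would raise their markers alike, but 2 others, ROBO4 and CDH5, were higher in SClav. Expression of these 3 genes by the adipocyte cultures themselves was not tested, and reads shared among myosin paralogs were not excluded for MYH2.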

How the results depend on the processing

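The alternatives named last in the processing summary were chosen only after the results were seen, and the cause of a change was not tested unless one is given. The interaction, with 1 gene, gave 0 with edgeR (RLE, upper-quartile or TMM), the stricter filter, voom, the test against 0.58, a pseudocount of 0.5, without libraries 17 and 18, and without or with a term for the shallow libraries. It gave 7 with DESeq2 and 2 with a pseudocount of 5. Unadjusted p-values under 0.05 were those of 346 genes with limma and 341 with edgeR, fewer than chance alone would give. DESeq2 gave 331 genes for NE in AbdSQ, 1067 and 1498 for the depots under saline and NE, and 253 shared NE genes. Voom gave 1750 for NE in SClav and 1251 for the depots under saline. The surrogate variable gave 272 for NE in AbdSQ, 984 and 1676 for the depots and 211 shared. The test against 0.58, which asks for larger changes, gave 89, 9, 143 and 171. With only the 10 libraries compared, NE in AbdSQ gave 14 and the depots under NE 501, while NE in SClav gave 881.

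Without libraries 17 and 18, NE in SClav gave 1453 and the depots under saline 980. Without the 4 shallow libraries, NE in SClav gave 89, the depots under NE 251 and the overlap 45, and fewer libraries account for part of this. All 50 choices of 2 NE and 4 saline SClav libraries, this one among them, gave a median of 160 (49 to 1572), and 15 of them gave 89 or fewer. The same choices in AbdSQ gave a median of 5 (1 to 1310). With a term for them NE in SClav gave 486 and the depots under NE 423. Each of the 20 libraries correlated best with its neighbour in sample number (r from 0.615 to 0.869 over 5000 genes), a hint from the data and not from the design. A block of consecutive numbers gave 6770, 4175 and 202 genes for NE in SClav, NE in AbdSQ and the interaction. The size of the excess in SClav and the small interaction count thus depend on treating the libraries as unrelated.

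Leaving out 1 library gave 503 to 982 genes for NE in SClav, 45 to 125 for NE in AbdSQ, 391 to 627 and 621 to 998 for the depots under saline and NE, 0 to 1 for the interaction and 43 to 109 shared genes; the libraries that moved these by over 1.5 times are named in the report. Lists called ranged over 4 to 10, 5 to 10, 4 to 8, 4 to 7 and 1 to 12 in the order of the comparisons. List counts went to 10 for NE in SClav without SClav NE library 6, to 9 or 10 for NE in AbdSQ without library 11, 15, 14 or 17, to 7 for the depots under NE without library 4 or 12, and for the interaction to 4, 5, 6 or 12 without library 9 or 12, 4 or 16, 20, and 17, and to 1 without 2, 3, 6, 7, 10, 11, 14, 15 or 19. With an estimated correlation 0, 0, 1, 1 and 0 lists were called in place of 6, 5, 6, 4 and 2, and with fry 0, 0, 7, 7 and 0. Between the depots under saline, fry called the posterior HOX, extracellular matrix, smooth muscle, interferon, positional, skeletal muscle and mesothelial lists. Under NE, fry called the posterior HOX, extracellular matrix, thermogenic, positional, macrophage, skeletal muscle and mesothelial lists. Without genes held by more than 1 list the depots under saline had 3.

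Named genes were followed under 5 settings (edgeR with RLE, edgeR with TMM, DESeq2, voom and the surrogate variable) and with each library left out, not under the filters, the 0.58 test, the shallow-library fits or the block. Of 790 values under the 5 settings 749 kept their direction and side of the threshold, 27 lost the call and 9 gained one. Of 1670 values with 1 library left out 1446 kept both, 219 lost the call and 2 gained one. Among called genes, 6 of 30 for the depots under NE, 8 of 56 under saline, 2 of 13 for NE in AbdSQ and 0 of 44 in SClav moved by over 1.5 times in fold, as the report names. The changes of sign were those of UCP1 with NE in AbdSQ: 0.36 (edgeR RLE), 0.35 (DESeq2), 0.19 (voom), 0.10 (surrogate variable), 0.34 (edgeR TMM), and 0.24, 0.55 and 0.17 without AbdSQ saline library 15, AbdSQ NE library 18 and AbdSQ NE library 20. With 1 library left out this value ranged from -0.54 to 0.55. UCP1 had few reads in AbdSQ, 39 over the saline and 49 over the NE libraries. Whether depth or the spread between libraries limits its estimate was not tested.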
